A study of Mus musculus with 8 samples.

How the data were processed

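RNA was sequenced from macrophages of mouse wound-bed skin, 3 libraries from day 1 and 5 from day 3 after injury. Per the labels' protocols, the excised tissue was minced and digested with collagenases, passed through a 70 µm strainer and selected with magnetic beads against F4/80, the macrophage surface protein encoded by Adgre1. Per the same protocols, each sample pooled 6 wounds from 3 mice. The protocols state 6 samples per time point, and the 8 libraries described here were those in hand. The labels do not say whether a mouse gave tissue to more than 1 pool, so p-values measure the spread between pools.

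The authors deposited a table of raw counts per gene, with 1 column per library and no normalisation. Per the file headers, reads were counted with featureCounts 1.6.0 on the Ensembl release 106 annotation of GRCm39, and the recorded command holds no option for strand, for read pairs or for reads with several positions. Trimmomatic and DESeq2 are named in the submitters' processing notes without versions, and the aligner is not given in the sources used here. Without strand, counts of a gene and of an overlapping partner cannot be told apart, and bases shared by both are not assigned. Low counts were mostly even: of counts from 2 to 20, between 73.0% and 86.0% were even in each library, so both reads of a pair were probably counted and the count overstates the number of fragments. The deposited columns carry the letters of the sample titles, whereas the alignments in the recorded command carry partly different letters, so the letters were used only as names in the main analysis. Total counts ran from 41566151 to 60289310 per library. A count of 3, taken as the floor of detection, corresponds to between 0.0498 and 0.0722 CPM (counts per library total, scaled as in edgeR), for counting error only.

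The table holds 55414 genes, of which 52081 (94.0%) were given a symbol through the reference name table. No column belonged to another sample. Genes were kept for testing with filterByExpr of edgeR (minimum count 10, with the day as group), scaled with TMM factors, and tested with the edgeR quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Every log2 fold change is day 3 minus day 1 and is given ± its standard error, and levels are mean normalised CPM ± SD (n = 3 and 5), the day 1 level before the day 3 level where both are given. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Members of 35 gene lists were counted as higher, lower or not called over all genes and adjusted over the list alone, and each list was compared with the other genes by camera with a preset inter-gene correlation of 0.01 and by camera with an estimated correlation. Each list was also tested on its own by fry, which asks whether its members move one way on balance, and p values of each test were adjusted over the 35 lists. Of 863 list symbols, 4 had no matching gene. Single values per library were compared by an exact permutation test, two-sided, over the 56 splits of 8 libraries into 3 and 5, whose smallest p is 0.0357, with adjustment over 24 measures.

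The tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule names the 10 highest and 10 lowest fold changes among called genes with an average log2 CPM of at least 5, day ranges that do not overlap and a symbol that is not a predicted gene. It also names up to 3 called members of each study or biology list or else its 2 most abundant members, the 2 most abundant members of each marker list, and Glul, Slc1a5, Cxcl1, Cxcl2, Cxcl5, Il1b, Arg1, Mrc1, Adgre1, Kdm6b and Ezh2 whatever their result. Some items that the rule names or that passed over a list alone are not reported here. Members that passed when adjusted over the list alone, and further genes given as examples from the stricter filter, were chosen after their values were seen.

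The alternatives were DESeq2, limma voom with and without library quality weights, RLE scaling, library totals alone, TMM without mitochondrial and the 10 most abundant genes, no filter on low counts, a stricter filter (at least 1 CPM in every library of 1 day and a mean of 5 CPM or more), other thresholds, each library left out, and the letters a to c with and without a block. The stricter filter was an alternative from the start. Its gene count was given a place beside the main count, with the rule for named genes applied to it and alternatives of its own, after the counts of all settings had been seen. Halved counts, a robust prior, and leaving out day 1 a and day 3 b together were added after the data had been seen.

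The fits were tested on simulated data drawn from the real means and library sizes, with 200 genes changed in either direction by 2-fold or 8-fold. The lysosome list was raised 2-fold as well (32 genes run with the default filter). Counts were drawn for each gene separately from dispersions estimated by edgeR, with no outlying library, so the simulation resembles these data only in part. In the simulated comparison of day 3 with day 1, edgeR with the default filter ran on 13964 genes and called 46 of 85 genes changed 8-fold (54.1%), 1 of 91 changed 2-fold and 0 of 13756 unchanged genes. With the stricter filter it ran on 7953 genes and called 50 of 60 (83.3%), 4 of 57 and 2 of 7805. On the 13964 genes DESeq2 called 61 of 85, 17 of 91 and 124 unchanged genes, and voom called 44 of 85, 3 of 91 and 4 unchanged genes. A gene was counted as detected in a library with 1 count or more.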

Results

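Gene expression was measured by bulk RNA sequencing in macrophages taken from mouse skin wounds 1 day and 3 days after injury. The series title concerns glutamine metabolism, neutrophil recruitment and epigenetic regulation during the resolution of inflammation, and its design sets day 3 against day 1. Each library came from F4/80 bead-selected cells of a pool of 6 wounds from 3 mice, with 3 libraries (a to c) at day 1 and 5 (a to e) at day 3. Total counts were 41566151, 60289310 and 53153029 at day 1 and 51957491, 51990542, 50515389, 56661695 and 51698117 at day 3. The mean total did not differ detectably between the days (exact permutation test, two-sided, p = 0.821, n = 3 and 5).

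The summed macrophage markers were higher in the day 3 libraries and the summed inflammatory monocyte markers lower. The macrophage identity markers summed to 30054 ± 3189 and 43544 ± 4358 CPM at day 1 and day 3 (SD, n = 3 and 5), and the monocyte markers to 12755 ± 656 and 8605 ± 1689 CPM. Most of the macrophage difference came from Lyz2, at 8167 ± 1609 and 19781 ± 2908 CPM, and the median log2 fold change of that list was 0.062. Much of the monocyte difference came from Thbs1, at 3813 ± 474 and 1742 ± 512 CPM, and the median of the monocyte list was -0.62. Fibroblast markers were sparse but higher at day 3, with 33.0 ± 14.7 and 108 ± 34.9 CPM, as were red cell markers, with 6.35 ± 1.51 and 15.1 ± 4.65 CPM, and B and plasma cell markers, with 76.9 ± 39.4 and 165 ± 41.3 CPM. Endothelial and pericyte markers were lower at day 3, with 61.5 ± 14.9 and 30.8 ± 10.5 CPM. In each of these sums the days did not overlap, which gave the smallest possible p of the exact permutation test, two-sided, 0.0357 (adjusted p = 0.0857 over 24 measures). None of the 24 measures passed after adjustment.

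The libraries also differed in how many genes had a count. A mean of 25924 ± 1773 genes was detected at day 1 and 16252 ± 2413 at day 3 (exact permutation test, two-sided, p = 0.0357, adjusted p = 0.0857, n = 3 and 5). Counts on 1776 chemosensory receptor genes, which are expressed in sensory epithelia, were found for 968, 928 and 597 genes in the day 1 libraries, for 474 in day 3 a, and for 64, 30, 21 and 26 in day 3 b to e. The 10 most abundant genes took 10.8% ± 1.01 of the counts at day 1 and 15.0% ± 0.620 at day 3 (p = 0.0357, adjusted p = 0.0857 by the same exact test). Neutrophil markers summed to 5955 CPM in day 3 b and to between 821 and 1120 CPM in the other day 3 libraries, and to 1435, 3533 and 5371 CPM in day 1 a, b and c. The first 3 principal components held 32.7%, 17.2% and 12.6% of the variance, with day 1 a at one end of the first and day 3 b at one end of the third.

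**Figure D1:**
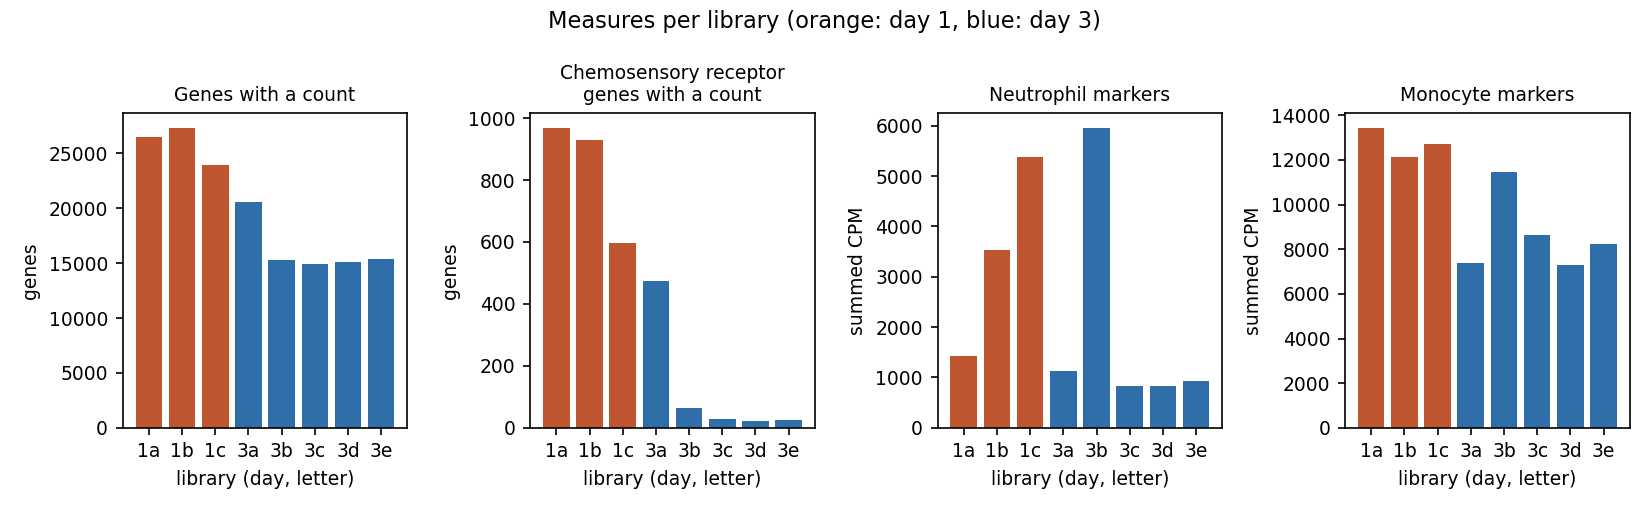
Bars give, for each of the 8 libraries (orange, day 1; blue, day 3), the number of genes with a count, the number of chemosensory receptor genes with a count, and the summed CPM of the neutrophil and of the monocyte markers. Detected genes run from 23928 to 27315 at day 1 and from 14952 to 20557 at day 3, and the neutrophil sum of day 3 b, 5955 CPM, stands above the other day 3 libraries.

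Chil3 and Slfn4 fell between day 1 and day 3. Chil3 (ENSMUSG00000040809, GRCm39 chromosome 3, 106054870 to 106074880), which encodes the chitinase-like protein Ym1, went from 1063 ± 543 to 148 ± 23.0 CPM (SD, n = 3 and 5), a log2 fold change of -2.85 ± 0.30. Slfn4 (ENSMUSG00000000204, chromosome 11, 83066012 to 83081042), a Schlafen gene that interferon induces in myeloid cells, went from 750 ± 168 to 202 ± 26.9 CPM, a log2 fold change of -1.89 ± 0.19. Both had an adjusted p of 0.0267 in the edgeR quasi-likelihood test, and both were lower in all 5 day 3 libraries than in any day 1 library. The call was lost for Chil3 and Slfn4 without day 1 a (adjusted p = 0.121 and 0.120), for Chil3 without day 1 c (0.0515), and for both without day 3 a (0.0635), day 3 c (0.136), day 3 d (0.141) or day 3 e (0.129), with edgeR throughout. With 1 library left out the log2 fold change ran from -3.15 to -2.39 for Chil3 and from -2.06 to -1.77 for Slfn4. Chil3 has a close paralogue, Chil4, at 1.87 ± 2.01 and 0.116 ± 0.0620 CPM at day 1 and day 3, and Slfn4 belongs to a gene family. Reads that match several copies may therefore have been misplaced or left out.

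These were the only genes called among 15371 tested, with 2414 at an unadjusted p under 0.05 and 735 at an adjusted p under 0.1, of which 553 were lower at day 3. The ranges of the days did not overlap for 2162 genes (14.1%), where chance gives a share of 0.0357. The median log2 fold change of all tested genes was -0.167, and with library totals alone it was -0.161. Among the 3710 genes with an average log2 CPM under 0 it was -0.730, and among the 2319 at 6 or more it was -0.0470. By edgeR the number of called genes was 0 without day 1 a, day 3 a, day 3 c, day 3 d or day 3 e (2877, 2345, 1976, 2000 and 2060 at an unadjusted p under 0.05), 1 without day 1 c, 31 without day 3 b and 59 without day 1 b. DESeq2 called 1021 genes (373 higher, 648 lower) and limma voom 825 (148 higher, 677 lower), both including Chil3 and Slfn4. On simulated counts DESeq2 also called 124 of 13756 unchanged genes, and voom 4. Those counts were drawn from dispersions estimated by edgeR, with no outlying library, so they do not tell how many calls in the real data are false.

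Among the more abundant genes, Mmp12, Apoe and Lyz2 were higher at day 3, and Retnla, Isg15 and Ly6c2 were lower. With the stricter filter on low counts, 146 of 8142 genes changed (63 higher, 83 lower; 1681 at an unadjusted p under 0.05). The ranges of the days did not overlap in 15.9% of the 8142, where chance gives a share of 0.0357. Among changed genes with an average log2 CPM of at least 5 and a symbol that is not a predicted gene or an accession, the 10 with the largest rise were Mmp12, Adgre4, Tmem176b, Tmem176a, Gngt2, S100a1, Clec12a, Apoe, Slc29a1 and Atraid. Mmp12, which encodes macrophage elastase (chromosome 9, 7344381 to 7369499), rose from 91.6 ± 88.5 to 662 ± 193 CPM, a log2 fold change of 2.85 ± 0.56 (edgeR adjusted p = 0.0355). With the default filter it was 2.83 ± 0.58, and 4.00 without day 1 b. Apoe, encoding a lipid carrier that macrophages secrete (chromosome 7, 19430034 to 19433113), rose from 8718 ± 4174 to 28547 ± 1294 CPM, by 1.71 ± 0.27 (adjusted p = 0.0263). With the same limits, the 10 with the largest fall were Retnla, Chil3, Sec61a1, Plk3, Bcl2l1, Rhov, Chmp4b, Por, Ly6c2 and Spon1. Of these, Sec61a1, Bcl2l1, Rhov and Chmp4b fell less without day 1 c: with the default filter their log2 fold changes were -2.40 ± 0.46, -2.27 ± 0.48, -2.25 ± 0.44 and -2.06 ± 0.39, and -1.59, -1.28, -1.60 and -1.24 without day 1 c. Retnla, a resistin-like gene induced by interleukin 4 (chromosome 16, 48662914 to 48664824), went from 178 ± 103 to 23.3 ± 3.78 CPM, a log2 fold change of -2.94 ± 0.37 (adjusted p = 0.0204), and Ly6c2, a surface marker of inflammatory monocytes, from 339 ± 159 to 86.5 ± 26.0 CPM, a log2 fold change of -1.97 ± 0.32 (adjusted p = 0.0263). Further genes among the 146, chosen after their values were seen, were Trem2 (1.37 ± 0.20), a lipid receptor of macrophages, Lyz2 (1.30 ± 0.19), Selenop (1.27 ± 0.24), Klf4 (1.05 ± 0.18), H2-Aa (1.06 ± 0.22) and Col1a1 (2.62 ± 0.43), all higher. Isg15 (-1.74 ± 0.27), Irf7 (-1.41 ± 0.25), Ppbp (-1.88 ± 0.26), Osm (-1.07 ± 0.19), Timp1 (-1.84 ± 0.30) and Pkm (-1.33 ± 0.29) were lower. Cthrc1, a gene of matrix-producing cells, had 0.0170 ± 0.0290 and 8.71 ± 4.01 CPM at day 1 and day 3, the first of these at the floor of detection.

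Some of these values are limited by shared sequence: Tmem176a and Tmem176b share 81 exon bases on opposite strands, Atraid shares 396 of its 2082 exon bases with Slc5a6, Gngt2 shares 234 of 1877 with Abi3, and Ly6c2 has a paralogue, Ly6c1, at 0.974 ± 0.365 and 2.04 ± 1.22 CPM at day 1 and day 3. All 146 had an adjusted p under 0.1 with the default filter, and DESeq2 and limma voom with that filter called 145 and 138 of them in the same direction. The edgeR count under the stricter filter was 0 without day 3 c, day 3 d or day 3 e (1375, 1406 and 1453 at an unadjusted p under 0.05), 17 without day 3 a, 99 without day 1 c, 183 without day 1 a, 152 without day 3 b and 390 without day 1 b.

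**Figure D2:**
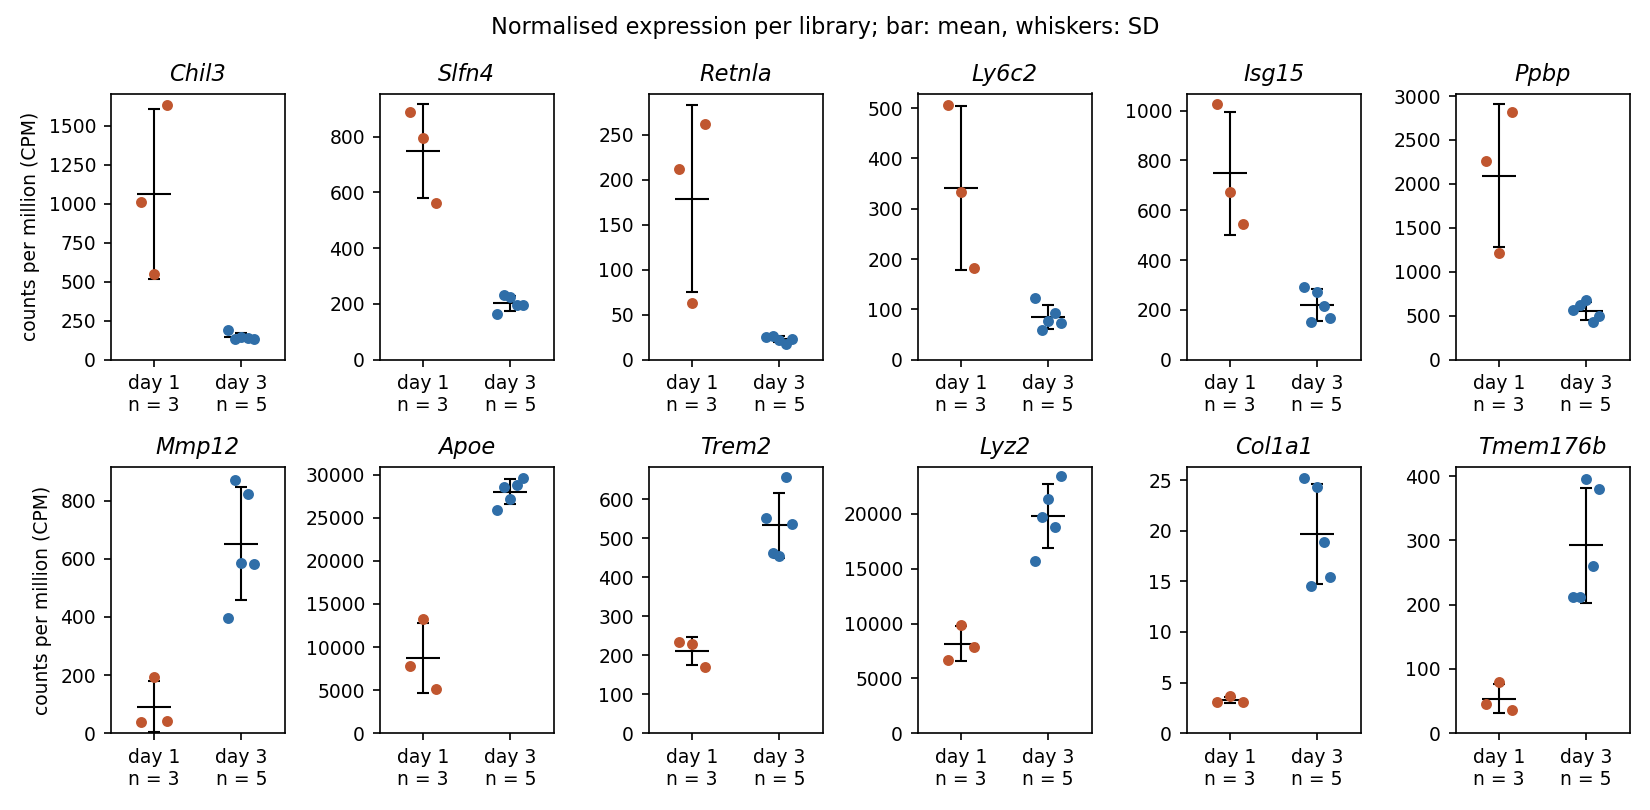
Each panel gives the normalised CPM of 1 gene in the 3 day 1 libraries (orange) and the 5 day 3 libraries (blue), with the mean as a bar and the SD as whiskers. The days do not overlap in any of the genes, which were chosen from those called under the stricter filter.

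Genes of glutamine transport, synthesis and use did not move as a group. Of 36 measured members, 0 were called over all genes by edgeR (7 at an unadjusted p under 0.05, and 2 higher and 3 lower by DESeq2, 1 and 1 by limma voom). When adjusted over the list alone, 2 were higher (Ctps2, 0.87 ± 0.23, and Glul), 3 were lower (Gpt2, Slc25a22, -2.62 ± 0.69, and Slc7a8, -2.13 ± 0.60) and 31 were not called. Gpt2, encoding mitochondrial alanine aminotransferase, which makes or uses glutamate, was at 42.9 ± 18.9 and 9.44 ± 2.77 CPM at day 1 and day 3, a log2 fold change of -2.19 ± 0.37, and it also fell under the stricter filter (edgeR adjusted p = 0.0304). Glul, encoding glutamine synthetase, was at 192 ± 108 and 408 ± 57.1 CPM (1.09 ± 0.32; edgeR adjusted p = 0.119 over all genes). The glutamine transporter gene Slc1a5 was at 20.8 ± 8.99 and 15.6 ± 10.4 CPM, and Slc3a2, the most abundant member, at 1065 ± 172 and 900 ± 78.3 CPM. The median log2 fold change of the list was -0.0087 (camera adjusted p = 0.985, and 0.983 with an estimated correlation) and its mean -0.37. With 1 library left out the median ran from -0.23 without day 1 b to 0.066 without day 3 b. With DESeq2 and limma voom values the list was not called either (camera adjusted p = 0.857 and 0.893).

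Genes that attract neutrophils had a median below 0, of a size that changed with the library left out. Of 17 measured members, 0 were called over all genes by edgeR (3 at an unadjusted p under 0.05, and 0 higher and 2 lower by DESeq2, 0 and 2 by limma voom). With values adjusted over the list alone, Ppbp and Cxcl3 were lower, 0 were higher and 15 were not called. Ppbp, a chemokine gene of platelets and myeloid cells, was at 2096 ± 809 and 556 ± 100 CPM at day 1 and day 3 (-1.91 ± 0.26), and Cxcl3 at 906 ± 701 and 170 ± 162 CPM (-2.41 ± 0.65). Cxcl2 was at 4366 ± 2705 and 2223 ± 1256 CPM (-0.97 ± 0.47; edgeR adjusted p = 0.362), Il1b at 1331 ± 755 and 851 ± 583 CPM (-0.65 ± 0.49) and Cxcl1 at 620 ± 285 and 806 ± 721 CPM (0.38 ± 0.62). Cxcl5 was at 89.8 ± 63.4 and 40.1 ± 22.1 CPM and Ccl4 at 1779 ± 653 and 1335 ± 544 CPM. The median log2 fold change of the list was -0.39 (camera adjusted p = 0.0945, and 0.640 with an estimated correlation). Without day 3 b, the library with the high neutrophil markers, the median was -1.08 (adjusted p = 9.63e-06), without day 1 a -0.74 (0.115) and without day 1 c -0.11 (0.901). With the stricter filter it was -0.38 (adjusted p = 0.0261). Neutrophils themselves express Cxcl2 and Il1b, and 12 of the 17 members were higher in day 3 b than in any other day 3 library.

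Enzymes that write and erase methyl marks on histones and DNA showed no shared change. Of 23 measured histone demethylase and TET genes and 35 histone and DNA methyltransferase genes, 0 were called by edgeR over all genes and 0 adjusted over the list alone. At an unadjusted p under 0.05 there were 2 and 2, DESeq2 called 1 and 1 lower and 0 higher, and limma voom called 0. Their median log2 fold changes were -0.19 (camera adjusted p = 0.977) and -0.092 (adjusted p = 0.974), and both had an adjusted p of 0.983 with an estimated correlation. With 1 library left out the medians ran from -0.28 without day 3 b to -0.067 without day 1 c, and from -0.30 without day 1 c to -0.041 without day 1 a. With DESeq2 values the camera adjusted p was 0.625 and 0.857, and with limma voom 0.888 and 0.892. Kdm6b, encoding a demethylase of a repressive histone mark, was at 138 ± 110 and 66.8 ± 13.6 CPM at day 1 and day 3 (-1.05 ± 0.41; edgeR adjusted p = 0.244). Ezh2, encoding the methyltransferase that sets that mark, was at 12.6 ± 4.50 and 8.45 ± 2.55 CPM. The most abundant members were the demethylase genes Jmjd1c (172 ± 51.5 and 191 ± 23.8 CPM) and Kdm7a (190 ± 51.6 and 151 ± 24.97 CPM), and Kmt2e (137 ± 25.2 and 131 ± 14.2 CPM) and Eed (80.4 ± 32.9 and 93.1 ± 28.6 CPM) on the methyltransferase side.

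Interferon-stimulated genes, antiviral effectors switched on by interferon, fell together. Their median log2 fold change over 35 members was -0.92 (camera adjusted p = 2.59e-14; adjusted p = 0.310 with an estimated correlation). Over all genes 0 members were called by edgeR (22 at an unadjusted p under 0.05, and 0 higher and 16 lower by DESeq2, 0 and 10 by limma voom). Once adjusted over the list alone, 20 were lower, 0 higher and 15 not called. Isg15 was at 748 ± 248 and 219 ± 62.5 CPM at day 1 and day 3 (-1.77 ± 0.27), Irf7 at 876 ± 211 and 322 ± 86.5 CPM (-1.44 ± 0.25), Rsad2 at 1080 ± 296 and 389 ± 113 CPM (-1.47 ± 0.27), and Ifit2, which was not called, at 822 ± 689 and 460 ± 158 CPM (-0.84 ± 0.53). Cmpk2 (-1.77 ± 0.29) and Oasl1 (-1.95 ± 0.37) were among the lower members.

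Other inflammatory mediators were also lower as a list, with a median of -0.51 over 37 members (camera adjusted p = 0.0273; adjusted p = 0.423 with an estimated correlation). Over all genes 0 were called by edgeR (9 at an unadjusted p under 0.05, and 1 higher and 6 lower by DESeq2, 1 and 4 by limma voom). Adjusted over the list alone 6 were lower, among them Osm (-1.10 ± 0.19), Ccl2 (-1.06 ± 0.24) and Cxcl10 (-1.65 ± 0.40), 1 was higher, the scavenger chemokine gene Cxcl16 (1.10 ± 0.25), and 30 were not called. Its most abundant members were Cd14 at 9329 ± 1532 and 9853 ± 3488 CPM and Ccl6 at 9877 ± 1658 and 7697 ± 1872 CPM. The list was not called without day 1 b (median -0.49, adjusted p = 0.173), day 1 c (-0.25, 0.461), day 3 c (-0.40, 0.0542), day 3 d (-0.40, 0.0675) or day 3 e (-0.42, 0.0524). Monocyte markers fell, with a median of -0.62 over 15 members (camera adjusted p = 0.000661; adjusted p = 0.225 with an estimated correlation). By edgeR 0 of them were called over all genes (5 at an unadjusted p under 0.05, and 0 higher and 5 lower by DESeq2, 0 and 3 by limma voom). When adjusted over the list alone, 5 were lower, Ly6c2 (-2.01 ± 0.33), Thbs1 (3813 ± 474 and 1742 ± 512 CPM), Plac8 (-0.94 ± 0.24), Vcan (-2.22 ± 0.59) and Cd177 (-4.45 ± 1.14), 0 were higher and 10 were not called. Clec4e was at 2339 ± 267 and 1783 ± 1371 CPM. Without day 1 c the monocyte median was -0.35 (adjusted p = 0.0309).

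Alternative-activation and repair genes moved in both directions. Of 30 members, edgeR called Chil3 alone over all genes (12 at an unadjusted p under 0.05, and 2 higher and 5 lower by DESeq2, 2 and 3 by limma voom). With values adjusted over the list alone, 6 were lower, 3 were higher and 21 were not called. Retnla (-2.97 ± 0.38), Ccl24 (-1.97 ± 0.42) and Arg1, the arginase gene (4024 ± 944 and 2017 ± 828 CPM, -0.997 ± 0.32), were lower, and Klf4 (1.02 ± 0.17), the growth factor gene Igf1 (96.9 ± 58.6 and 261 ± 70.9 CPM, 1.43 ± 0.40) and the lectin gene Clec10a (0.84 ± 0.27) were higher. The mannose receptor gene Mrc1 was at 1328 ± 535 and 984 ± 199 CPM (-0.43 ± 0.26). The list median was -0.33 (camera adjusted p = 0.444, and 0.551 with an estimated correlation). The median ran from -0.36 without day 3 c to 0.14 without day 1 c with 1 library left out. Resident skin macrophage markers had a median of -0.30 over 14 members (camera adjusted p = 0.977, and 0.983 with an estimated correlation, and leave-one-out medians from -0.46 without day 1 b to -0.048 without day 1 a). Over all genes edgeR called 0 (3 at an unadjusted p under 0.05, and 1 higher and 2 lower by DESeq2, 1 and 1 by limma voom). Once adjusted over the list alone, Selenop was higher (1573 ± 495 and 3716 ± 519 CPM), Ccl24 and Cd163 were lower, and 11 were not called, Ccl8 being at 1894 ± 660 and 2163 ± 961 CPM.

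Genes of apoptotic cell uptake and cholesterol handling moved in both directions. Of 35 members 0 were called over all genes by edgeR (9 at an unadjusted p under 0.05, and 3 higher and 1 lower by DESeq2, 2 and 0 by limma voom). Adjusted over the list alone Trem2 (211 ± 36.2 and 533 ± 82.8 CPM, 1.34 ± 0.19) and Apoe (8724 ± 4116 and 28039 ± 1480 CPM, 1.68 ± 0.29) were higher, the transglutaminase gene Tgm2 was lower (-1.42 ± 0.36) and 32 were not called. Lgmn was at 7841 ± 2551 and 8367 ± 439 CPM. Camera placed the list above the other genes (adjusted p = 0.0321; adjusted p = 0.310 with an estimated correlation), while its median was -0.016 and its mean -0.037, both below 0 but above the median of all genes. It was not called without day 1 a (median 0.053, adjusted p = 0.0538), day 1 b (0.10, 0.0528), day 1 c (0.21, 0.0656), day 3 a (0.077, 0.0597), day 3 d (0.024, 0.0780) or day 3 e (-0.048, 0.0524), nor with DESeq2 values (0.0532). Its median was 0.15 without day 3 b and 0.029 without day 3 c. Genes of the synthesis and receptors of pro-resolving lipid mediators were higher as a list, with a median of 0.29 over 15 members (camera adjusted p = 0.0139, and 0.310 with an estimated correlation). Of its 21 genes, Alox15, Alox12, Gpr37, Ptgds, Ephx2 and Lgr6 had too few counts to be tested. Over all genes edgeR called 0 of the 15 (4 at an unadjusted p under 0.05, and 3 higher and 1 lower by DESeq2, 2 and 0 by limma voom). When adjusted over the list alone, Anxa1, encoding annexin A1 (1182 ± 370 and 2179 ± 140 CPM), and Hpgds (1.68 ± 0.44) were higher, the leukotriene receptor gene Ltb4r1 was lower (-1.26 ± 0.33) and 12 were not called. Pla2g7 was at 1357 ± 515 and 1628 ± 199 CPM. That call was lost without day 1 a (median 0.27, adjusted p = 0.0621) and with the stricter filter (adjusted p = 0.0579), and without day 1 b the median was 0.48.

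Antigen presentation genes of MHC class II rose as a list, with a median of 0.70 over 15 members (camera adjusted p = 0.000105; adjusted p = 0.310 with an estimated correlation). Over all genes 0 were called by edgeR (8 at an unadjusted p under 0.05, and 2 higher and 0 lower by DESeq2, 1 and 0 by limma voom). With values adjusted over the list alone, H2-Aa (919 ± 223 and 1881 ± 340 CPM, 1.03 ± 0.22) and H2-DMb1 (0.84 ± 0.24) were higher, 0 were lower and 13 were not called. Cd74, the invariant chain, was at 7505 ± 3459 and 12188 ± 2782 CPM and Ctss at 7421 ± 2850 and 12441 ± 705 CPM. Without day 1 c the median was 0.45 (adjusted p = 0.0124). Matrix proteases, their inhibitors and matrix proteins moved in both directions, with a median of -0.17 over 26 members (camera adjusted p = 0.963, and 0.983 with an estimated correlation, and leave-one-out medians from -0.33 without day 3 b to 0.22 without day 1 c). Of these 0 were called over all genes by edgeR (8 at an unadjusted p under 0.05, and 2 higher and 6 lower by DESeq2, 1 and 4 by limma voom). Once adjusted over the list alone, Mmp12 (2.83 ± 0.58) and Sparc (2.35 ± 0.57) were higher, 6 were lower, among them Timp1 (-1.87 ± 0.30), Mmp19 (-1.18 ± 0.23) and Adam8 (-1.47 ± 0.31), and 18 were not called. Ctsb was at 15831 ± 2937 and 17908 ± 1199 CPM. Lysosomal genes had a median of -0.054 over 32 members (camera adjusted p = 0.411, and 0.640 with an estimated correlation, and leave-one-out medians from -0.061 without day 3 d to 0.016 without day 1 b). By edgeR 0 of them were called over all genes (12 at an unadjusted p under 0.05, and 3 higher and 0 lower by DESeq2, 3 and 0 by limma voom). Adjusted over the list alone 2 were higher, among them Ctsh (0.58 ± 0.14), 0 were lower and 30 were not called. Psap was at 5730 ± 434 and 5474 ± 1241 CPM and Cd68 at 3168 ± 1237 and 3697 ± 429 CPM.

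Camera with the preset correlation, but not with an estimated one, called glycolysis genes lower and genes of the respiratory chain higher as lists, the former not without day 1 c. The 22 glycolysis members had a median of -0.61 (camera adjusted p = 0.000368; adjusted p = 0.505 with an estimated correlation). Over all genes edgeR called 0 of them (8 at an unadjusted p under 0.05, and 0 higher and 2 lower by DESeq2, 0 and 1 by limma voom). When adjusted over the list alone, the pyruvate kinase gene Pkm (2748 ± 1290 and 1077 ± 281 CPM), Hk3 (-1.45 ± 0.34) and the lactate exporter gene Slc16a3 (284 ± 420 and 28.5 ± 7.78 CPM) were lower, 0 were higher and 19 were not called, Eno1 being at 2770 ± 507 and 1833 ± 403 CPM. Without day 1 c the glycolysis median was -0.29 (adjusted p = 0.144). The summed CPM of the list was 16441 in day 1 c against 8200 in day 1 a and 9118 in day 1 b, and 20 of the 22 members were higher in day 3 b than in any other day 3 library. The 44 nuclear genes of oxidative phosphorylation had a median of 0.25 (camera adjusted p = 1.9e-05; adjusted p = 0.310 with an estimated correlation). Of these 0 were called over all genes by edgeR (16 at an unadjusted p under 0.05, and 6 higher and 1 lower by DESeq2, 1 and 1 by limma voom). With values adjusted over the list alone, 6 were higher, such as Cox6c (0.67 ± 0.16) and Ndufa6 (0.71 ± 0.18), Atp5b was lower (-0.72 ± 0.18) and 37 were not called. Uqcrc1 was at 411 ± 94.97 and 440 ± 39.6 CPM and Cox4i1 at 311 ± 51.9 and 350 ± 25.6 CPM. Fatty acid oxidation genes had a median of 0.19 over 20 members (camera adjusted p = 0.0576, and 0.387 with an estimated correlation). Over all genes edgeR called 0 (2 at an unadjusted p under 0.05, and 2 higher and 0 lower by DESeq2, 1 and 0 by limma voom). Once adjusted over the list alone, Acadm was higher (0.93 ± 0.19), 0 were lower and 19 were not called; Etfa was at 212 ± 76.9 and 276 ± 38.3 CPM and Slc25a20 at 86.3 ± 14.5 and 89.1 ± 7.33 CPM. The list was called without day 1 a (median 0.34, adjusted p = 0.0261) and without day 3 b (0.27, adjusted p = 0.0285), and without day 1 b its median was 0.011 (adjusted p = 0.125). Tricarboxylic acid cycle genes had a median of 0.057 over 27 members (camera adjusted p = 0.193, and 0.387 with an estimated correlation, and leave-one-out medians from 0.017 without day 3 c to 0.12 without day 3 d), none of them called over all genes or adjusted over the list alone (4 at an unadjusted p under 0.05, and 2 higher and 0 lower by DESeq2, 0 and 0 by limma voom), with Mdh2 at 509 ± 162 and 384 ± 23.8 CPM and Sdhb at 321 ± 105 and 407 ± 55.3 CPM.

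Hypoxia targets had a median of 0.31 over 24 members (camera adjusted p = 0.0394; adjusted p = 0.640 with an estimated correlation). None was called over all genes or adjusted over the list alone (4 at an unadjusted p under 0.05, and 1 higher and 2 lower by DESeq2, 0 and 1 by limma voom). Plin2 was at 3718 ± 1510 and 3363 ± 204 CPM and Anxa2 at 2351 ± 466 and 1547 ± 209 CPM. Of the 24 members, 22 were higher in day 3 b than in any other day 3 library. The median was -0.026 without day 1 a (adjusted p = 0.434) and 0.10 without day 3 b (adjusted p = 0.258). The call was also lost with the stricter filter (adjusted p = 0.216) and with DESeq2 values (0.177). Genes of the amino acid stress response had a median of -0.31 over 19 members (camera adjusted p = 0.561, and 0.668 with an estimated correlation, and leave-one-out medians from -0.47 without day 3 b to -0.20 without day 3 c). By edgeR 0 were called over all genes (3 at an unadjusted p under 0.05, and 1 higher and 1 lower by DESeq2, 0 and 1 by limma voom) and, adjusted over the list alone, Aars was lower (-1.08 ± 0.25), 0 were higher and 18 were not called. Nars was at 468 ± 280 and 437 ± 65.5 CPM and Ppp1r15a at 398 ± 102 and 361 ± 73.1 CPM. Cell cycle genes had a median of -0.060 over 36 members (camera adjusted p = 0.453, and 0.663 with an estimated correlation, and leave-one-out medians from -0.36 without day 3 a to 0.14 without day 1 a). None was called over all genes or adjusted over the list alone (0 at an unadjusted p under 0.05, and 0 higher and 0 lower by DESeq2, 0 and 0 by limma voom). Pcna was at 101 ± 54.6 and 105 ± 16.6 CPM and Mcm6 at 39.4 ± 21.2 and 39.2 ± 13.02 CPM.

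**Figure D3:**
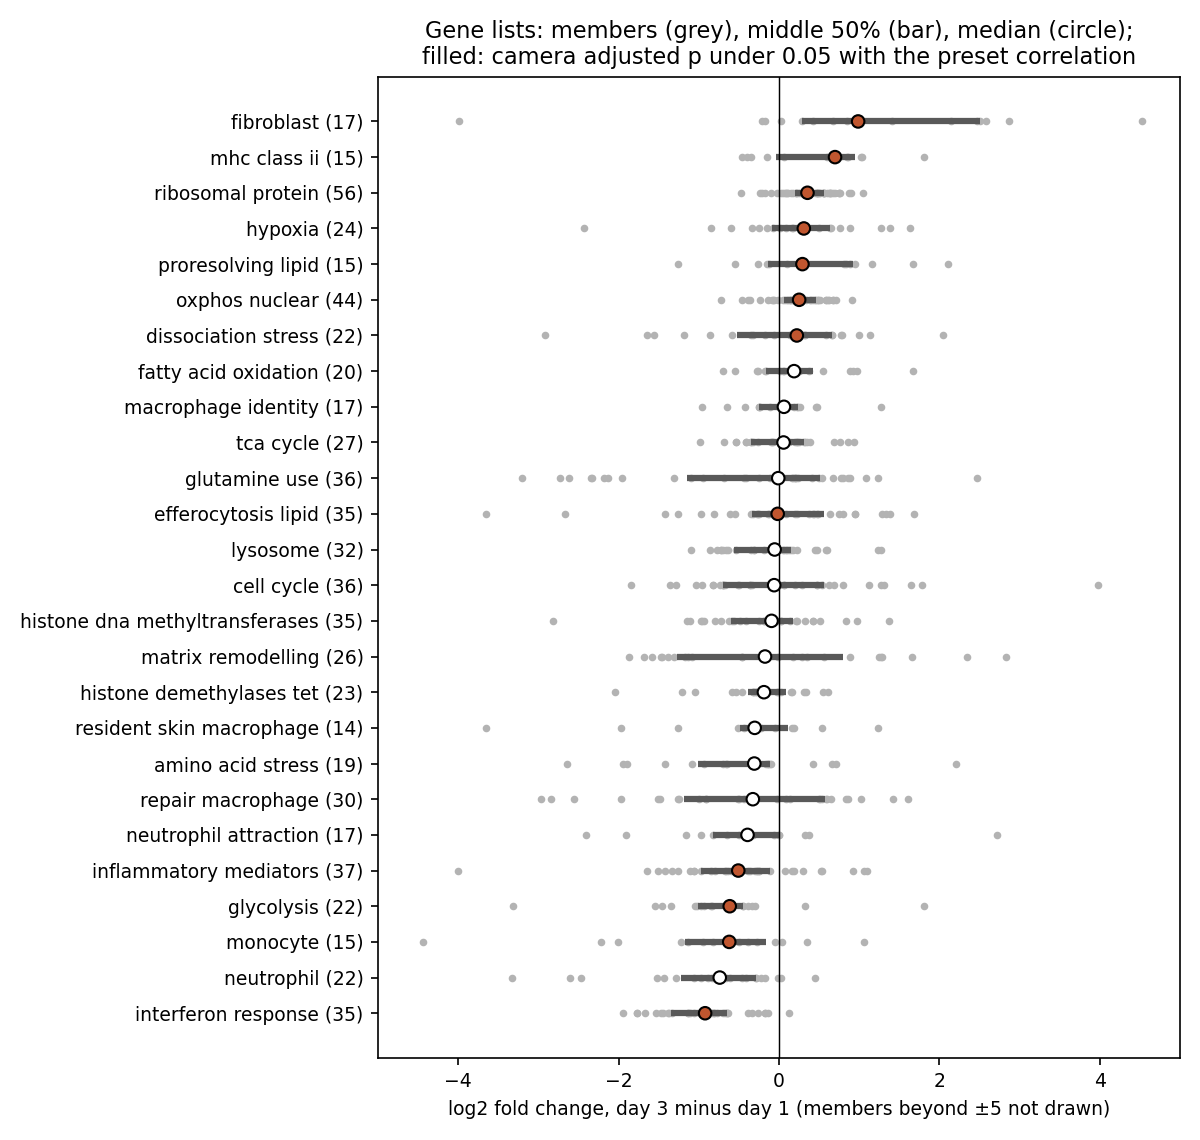
Each line of the plot gives the log2 fold changes (day 3 minus day 1) of the tested members of 1 list as grey points, the middle 50% of them as a bar and their median as a circle, filled where camera with the preset correlation gave an adjusted p under 0.05. Lists of most other cell types, B and plasma cells included, are not drawn, and of the filled medians drawn the interferon list has the lowest, -0.92, and the fibroblast list the highest, 0.99.

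Macrophage identity markers had a median of 0.062 over 17 members (camera adjusted p = 0.193, and 0.423 with an estimated correlation, and leave-one-out medians from -0.027 without day 1 a to 0.16 without day 1 c). Over all genes 0 were called by edgeR (4 at an unadjusted p under 0.05, and 3 higher and 1 lower by DESeq2, 2 and 1 by limma voom). Adjusted over the list alone Lyz2, encoding lysozyme, was higher (8167 ± 1609 and 19781 ± 2908 CPM), the Fc receptor gene Fcgr1 was lower (-0.96 ± 0.17) and 15 were not called. Adgre1, whose product the beads bind, was at 819 ± 126 and 1129 ± 76.3 CPM (0.46 ± 0.15; edgeR adjusted p = 0.170). The list was called without day 1 c (median 0.16, adjusted p = 0.0459). Ribosomal protein genes rose as a list, with a median of 0.36 over 56 members (camera adjusted p = 3.67e-12; adjusted p = 0.423 with an estimated correlation). By edgeR 0 of them were called over all genes (22 at an unadjusted p under 0.05, and 11 higher and 0 lower by DESeq2, 6 and 0 by limma voom). When adjusted over the list alone, 10 were higher, such as Rpl35 (1.05 ± 0.17), 0 were lower and 46 were not called. Rpl4 was at 484 ± 23.1 and 598 ± 75.8 CPM and Rplp0 at 454 ± 160 and 591 ± 90.4 CPM. Many of these genes have processed pseudogenes that can match the same reads, which may have been misplaced or left out. The ribosomal median was 0.23 without day 1 a and 0.58 without day 1 c. Immediate early and heat shock genes that tissue digestion induces had a median of 0.22 over 22 members (camera adjusted p = 0.0235; adjusted p = 0.581 with an estimated correlation) and a mean of -0.042. Over all genes edgeR called 0 of them (8 at an unadjusted p under 0.05, and 5 higher and 1 lower by DESeq2, 3 and 0 by limma voom). With values adjusted over the list alone, 5 were higher, such as Dusp1 (3698 ± 1173 and 7413 ± 1571 CPM) and Klf6 (2594 ± 488 and 4476 ± 77.3 CPM), 2 were lower, Junb and Ier3, and 15 were not called. That call was lost without day 1 a (median -0.070, adjusted p = 0.297), day 3 d (0.16, 0.0616) or day 3 e (0.23, 0.0524), and with the stricter filter (adjusted p = 0.179). The median was 0.57 without day 1 c and 0.036 without day 1 b.

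Fibroblast markers rose as a list from a low level, with a median of 0.99 over 17 members (camera adjusted p = 0.00151; adjusted p = 0.310 with an estimated correlation). Of these 0 were called over all genes by edgeR (5 at an unadjusted p under 0.05, and 5 higher and 0 lower by DESeq2, 1 and 0 by limma voom). Once adjusted over the list alone, the collagen genes Col1a1 (3.27 ± 0.318 and 19.7 ± 4.90 CPM), Col1a2 (2.51 ± 0.62) and Col3a1 (4.41 ± 2.48 and 24.4 ± 12.4 CPM) were higher, 0 were lower and 14 were not called. The median was 1.64 without day 1 a and 2.16 without day 1 b, and over 21 alternatives it ran from 0.51 to 2.51. The fibroblast call was lost with limma voom with library quality weights (camera adjusted p = 0.0552). Only 3 B and plasma cell markers were measured, with a median of 1.80 (camera adjusted p = 0.0294; adjusted p = 0.310 with an estimated correlation) and none called over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05, and 0 higher and 0 lower by DESeq2, 0 and 0 by limma voom), Ighm being at 71.4 ± 37.4 and 138 ± 36.2 CPM and Cd79b at 5.23 ± 7.10 and 25.5 ± 6.84 CPM. That call was lost without day 1 a (median 1.20, adjusted p = 0.182), day 1 b (1.16, 0.468), day 1 c (3.81, 0.0709) or day 3 a (1.81, 0.0549), and with DESeq2 values (0.0682). The B and plasma cell median was 1.09 without day 3 b. Neutrophil markers had a median of -0.74 over 22 members (camera adjusted p = 0.0541, and 0.668 with an estimated correlation). None was called over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05, and 0 higher and 0 lower by DESeq2, 0 and 1 by limma voom). S100a8 was at 898 ± 632 and 485 ± 722 CPM and Il1r2 at 475 ± 165 and 407 ± 402 CPM. The neutrophil list was called without day 1 a (median -1.24, adjusted p = 0.0112) and without day 3 b (-2.03, adjusted p = 4.16e-10), and with the stricter filter (-0.79, adjusted p = 0.0261). Without day 1 c its median was -0.19 (adjusted p = 0.718).

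The other cell type lists were not called by camera, for which adjusted p-values are given first with the preset and then with an estimated correlation, and no member was called over all genes by edgeR. Dendritic and Langerhans cell markers had a median of -0.66 over 11 members (adjusted p = 0.461 and 0.663), with Itgae, near the floor of detection, the only one called adjusted over the list alone, lower at day 3. That median ran from -1.24 without day 3 b to -0.016 without day 1 a with 1 library left out. Ccr7 was at 103 ± 55.8 and 47.5 ± 37.3 CPM and Cd209a at 11.8 ± 2.91 and 23.9 ± 7.15 CPM. T and NK cell markers had a median of 0.16 over 14 members (adjusted p = 0.944 and 0.940). The median ran from -0.34 without day 3 c to 0.99 without day 1 c with 1 library left out. Il7r was at 228 ± 112 and 124 ± 33.9 CPM and Cd2 at 10.4 ± 8.12 and 7.76 ± 1.15 CPM. Mast cell, eosinophil and basophil markers had a median of -1.67 over 6 members (adjusted p = 0.0576 and 0.310). Hdc was at 470 ± 299 and 150 ± 122 CPM and Ccr3 at 7.54 ± 5.25 and 4.01 ± 2.42 CPM. The list was called without day 3 b (-1.40, adjusted p = 0.04995). Keratinocyte markers had a median of 1.40 over 9 members (adjusted p = 0.375 and 0.624), with Dsp, near the floor, the only one called adjusted over the list alone, lower at day 3. That median ran from 0.38 without day 3 b to 2.94 without day 1 b with 1 library left out. Krtdap was at 0.544 ± 0.881 and 6.79 ± 13.1 CPM and Sfn at 1.66 ± 1.93 and 4.38 ± 5.13 CPM. Endothelial and pericyte markers had a median of -1.29 over 6 members (adjusted p = 0.102 and 0.351), with Flt1 the only one called adjusted over the list alone, at 4.59 ± 2.38 and 0.129 ± 0.158 CPM at day 1 and day 3. The median ran from -1.63 without day 3 c to -0.43 without day 1 b with 1 library left out. Pecam1 was at 21.6 ± 8.97 and 16.4 ± 4.98 CPM and Kdr at 20.4 ± 21.8 and 3.21 ± 2.90 CPM. Muscle markers had a median of 0.34 over 8 members (adjusted p = 0.457 and 0.663). That median ran from -0.67 without day 3 b to 0.95 without day 1 b with 1 library left out. Tnni2 was at 1.49 ± 1.21 and 5.43 ± 2.15 CPM and Mylpf at 2.51 ± 2.44 and 3.73 ± 1.59 CPM. Red cell markers had a median of 1.23 over 5 members (adjusted p = 0.0911 and 0.423). Bpgm was at 3.02 ± 1.97 and 7.10 ± 2.31 CPM and Hba-a1 at 1.42 ± 0.693 and 2.97 ± 2.21 CPM. This list was called without day 3 c (1.29, adjusted p = 0.0423). Adipocyte, Schwann cell and melanocyte markers had a median of 1.95 over 5 members (adjusted p = 0.0945 and 0.505). Mbp was at 17.2 ± 2.06 and 15.8 ± 5.36 CPM and Car3 at 2.26 ± 3.09 and 8.74 ± 8.17 CPM. The adipocyte list was called without day 3 e (2.20, adjusted p = 0.0188), and its median ran from -0.23 without day 1 c to 4.67 without day 1 a. Of the 13 lists that camera called, none was called with an estimated correlation. Of those 13, fry, which tests whether members move one way on balance, called the monocyte list and the B and plasma cell list. Of the others it called the mast cell, eosinophil and basophil list and the endothelial and pericyte list, both lower at day 3 (adjusted p = 0.0122 for each of the 4).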

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

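The tests of genomic DNA, of depth and of time behind the sparse counts, and of neutrophils and of a wrong label behind day 3 b, were chosen only after those results were seen. In the 5 day 3 libraries, a library was set apart where its gap to the nearest other library exceeded 0.71 of the whole range. This happened in 26 of 162 measures, where chance gives about 1 in 20, or 8.1. Of the 26, 17 were in day 3 b, 6 in day 3 a, 2 in day 3 c and 1 in day 3 d. The 3 day 1 libraries were too few for this rule.

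Day 3 a had counts on more genes than the other day 3 libraries: 20557 genes detected against 14952 to 15359, 14513 genes with at least 10 counts against 12763 to 13148, and 474 chemosensory receptor genes detected against 21 to 64. These receptors took 129 CPM of its counts against 10.1 to 26.4 CPM. Day 3 a was also highest for Chil3, at 188 CPM against 134 to 145, and for Rpl4, at 730 CPM against 541 to 589. Rpl4 in the day 1 libraries was at 458 to 498 CPM.

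Counts on genes silent in most day 3 libraries were found in the 3 day 1 libraries and in day 3 a. Depth is argued against: with all libraries thinned to the lowest total, the lowest day 1 library still had counts on 586 chemosensory receptor genes and the highest of day 3 b to e on 61. Genomic DNA in the library is a candidate explanation, since it would give X-linked silent genes fewer counts than autosomal ones in animals with 1 X: the highest ratio of X to autosome in the 4 libraries was 0.789 for counts per kb, whose intervals were too wide to decide (0.319 to 1.47 in day 3 a), and 0.612 for detection rates per kb, a version added afterwards, with no interval reaching above 0.765. Low transcription across the genome would give the same ratio, the labels give no sex, and Xist was near 0 with Ddx3y between 89.8 and 170 CPM in every library. Time after injury stays open and cannot be told apart from library preparation, because 3 of the 4 libraries are all of day 1, while day 3 a, with 458 receptor genes after thinning, shows that time alone leaves the pattern unexplained.

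Day 3 b had the highest neutrophil sum, 5955 CPM against 821 to 1120, the highest mast cell, eosinophil and basophil sum, 370 CPM against 89.0 to 130, and the highest keratinocyte sum, 74.6 CPM against 4.94 to 9.63. It was highest for Cd14 (15851 CPM against 7067 to 9555), Thbs1 (2649 against 1453 to 1626), Clec4e (4221 against 1016 to 1422), S100a8 (1773 against 115 to 253), Il1r2 (1123 against 179 to 279) and Hdc (366 against 81.2 to 126). The same held for Cxcl1 (2057 CPM against 324 to 787), Il1b (1889 against 543 to 691) and Cxcl3 (459 against 84.0 to 111), and for the keratinocyte genes Krtdap (30.2 against 0 to 1.73) and Sfn (13.3 against 0.590 to 4.03). It was lowest for Selenop (2806 CPM against 3804 to 4064), Bpgm (3.01 against 7.63 to 8.50) and Adgre1 (994 against 1149 to 1181). Of the mast cell, eosinophil and basophil sum of day 3 b, 370 CPM, Hdc alone made up 366 CPM. That sum and Hdc are therefore not separate observations, and the sum does not speak for the list.

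Neutrophils carried over in the F4/80 bead selection stay open for day 3 b. Of 22 tested neutrophil markers, 21 (95.5%) were highest there, with a median ratio of 11.5 to the other day 3 libraries, but the sum of these markers had prompted the test, and 91.7% of hypoxia targets and 90.9% of glycolysis genes were highest there too (median ratios 1.69 and 1.55). The selection should remove such cells, and several of these genes are also expressed by inflammatory macrophages. A day 1 library carrying a day 3 label stays open. On the 100 genes of lowest p in a fit without the library placed, its median position from the day 1 mean (0) to the day 3 mean (1) was 0.649, against 0.302, 0.548 and 0.270 in day 1 and 0.884 to 1.01 in the other day 3 libraries. This lies above 0.5 and above every day 1 library, but above day 1 b by less than the SD between the day 1 positions. A first version, on 152 called genes, gave 0.749. In a further test, added when this one had not decided, day 3 b lay beyond the day 1 range on the side of day 3 in 78.0% of the 100 genes, but day 1 b, placed against the other day 1 libraries, did so in 92.0%, so neither test excludes a wrong label. Other values go against it: day 3 b detected 15320 genes, where day 1 had 23928 or more, and 64 chemosensory receptor genes, where day 1 had 597 or more, though day 3 a shows that these counts also vary within a day. Apoe was at 28582 CPM (at most 13219 in day 1), Chil3 at 135 (548 or more) and Slfn4 at 231 (564 or more). These 3 genes carry no weight here: they were named for day ranges that do not overlap, with day 3 b counted as day 3. On the first principal component day 3 b, at 81.3, lay near day 3 c to e (89.7 to 94.7). Day 3 a was at 0.76 there and day 1 at -232 to -35.4. That component ranked the libraries much as the number of detected genes did. It, the detected genes and the receptor genes are therefore not separate observations. Correlations of day 3 b were higher with every other day 3 library than with any day 1 library, but decide little. They were 0.866 to 0.873 with day 3 c to e, but 0.842 with day 3 a, close to the 0.840 with day 1 c (0.724 and 0.804 with day 1 a and b). The monocyte sum, 11448 CPM, was nearer to day 1 (12122 to 13431) than to the other day 3 libraries (7300 to 8641). It holds Clec4e and Thbs1, given above, so it is no separate observation and does not speak for the list. Of the 15 monocyte markers, 6 were highest in day 3 b among the day 3 libraries. Ly6c2 was lowest there, at 59.1 CPM with the stricter filter, against 74.7 to 127 in the other day 3 libraries. No biological explanation for a single day 3 library was tested.

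The rise of ribosomal protein genes, with a median of 0.36, lay above random lists matched on gene length or GC content: the highest of the middle 95% of medians was 0.213 for exon length and 0.072 for GC content. For the nuclear genes of oxidative phosphorylation, with a median of 0.25, lists matched on GC content reached 0.115. A length effect may account for that median, since lists matched on exon length reached 0.278. Exon length covered all annotated exons of a gene, which can exceed the length of the expressed transcript. Members were drawn singly, which leaves out the correlation between list members (estimated at 0.626 and 0.140) and makes these limits too narrow. Neither bias is therefore excluded for either list. Reads shared with pseudogenes were not tested.

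In day 3 c, Cd2 was lowest, at 5.78 CPM against 7.97 to 8.67, and Col3a1 highest, at 46.4 CPM against 17.2 to 20.7. In day 3 d the total count was highest, 56661695 against 50515389 to 51990542.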

How the results depend on the processing

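Halved counts, a robust prior, leaving out day 1 a and day 3 b together, and all alternatives to the count under the stricter filter were chosen after the data had been seen. Chil3 and Slfn4 were the 2 genes changed. DESeq2 called 1021, limma voom 825, voom with library quality weights 990, edgeR with no filter on low counts 1347, with the stricter filter 146, with halved counts 46, with a robust prior 12, and without day 1 a and day 3 b together 25. RLE scaling, library totals alone, TMM without the most abundant genes and a 2-fold minimum gave 2. Leaving out 1 library gave 0 to 59, an adjusted p under 0.01 gave 0, the replicate block on letters a to c gave 0 (1343 at an unadjusted p under 0.05) and the same libraries with no block 0 (1660). The cause was not tested, except that the block and leaving out a library leave fewer libraries.

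The stricter filter gave 146 changed genes. Other tools with that filter gave 732 (DESeq2, 144 of them among the 146), 219 (limma voom, 133 among the 146) and 120 (limma voom with library quality weights, 88 among the 146). Leaving out 1 library gave 0 to 390, and 138 of the 390 without day 1 b and 55 of the 99 without day 1 c were among the 146. Further settings gave 0 (replicate block), 0 (letters a to c with no block), 297 (without day 1 a and day 3 b) and 2 (adjusted p under 0.01). The cause was not tested. Deviations from the day mean correlated across genes by 0.0857, 0.0267 and 0.0006 between libraries of 1 title letter. Between libraries of different title letters they correlated by -0.143 to 0.105, so the title letters gave no sign of pairing. The alignments in the recorded command carry partly different letters. If they stand in the order of the columns, letter a joins day 1 a with day 3 a (0.0857). Letter f then joins day 1 c with day 3 e (0.105). No other libraries correlated as highly across the days, so pairing by the alignment letters stays open. A block on those letters was not run.

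The neutrophil attraction median of -0.39 passed camera's threshold with the stricter filter (-0.38, adjusted p = 0.0261), halved counts (-0.40, 0.0399) and without day 1 a and day 3 b together (-1.40, 1.15e-05), and ran from -0.11 (without day 1 c) to -1.08 (without day 3 b) with 1 library left out. The other 3 study lists stayed uncalled under every alternative. Over 31 other lists, 607 of 710 values kept their side of the threshold, 69 lost a call, 33 gained one and 1 reversed in the direction camera gave: hypoxia without day 1 a and day 3 b together (-0.11, adjusted p = 0.871). The median itself changed sign in 49 of the 710, over 16 lists: 38 of those counted as kept, 10 of those that lost a call (such as B and plasma cells with no filter, -1.96) and the 1 reversed. The interferon, MHC class II, oxidative phosphorylation, monocyte and ribosomal lists kept their call in all 21 alternatives, leaving aside the set tests with an estimated correlation and fry. Over 138 named gene results, 2497 of 2893 values kept their side, 16 lost a call, 380 gained one and 0 reversed. Among those counted as kept, 67 values of 23 genes changed sign with neither value called. Depth limits genes under 0.0498 to 0.0722 CPM, the level of 3 counts.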

Other observations

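The test of endoplasmic reticulum genes was chosen only after the result was seen, and the counts over splits were planned. Several genes that serve protein entry into the endoplasmic reticulum and folding there were among those lower at day 3 under the stricter filter, such as Sec61a1 (-2.37 ± 0.45), which encodes the translocation channel, the chaperone genes Calr (-1.51 ± 0.29) and Pdia6 (-1.21 ± 0.24), and Dnajb11 (-0.95 ± 0.18). A list of 40 such genes was written after 8 of them had been seen. Over all libraries its median log2 fold change was -0.76, with 36 members below 0 (camera p = 3.1e-11, and 0.101 with an estimated correlation), and without day 1 c it was -0.34 (p = 3.46e-05, and 0.0525). The whole list met the bound set first. Since 8 members had prompted the list, the deciding test was then moved to the other 32, with a changed bound. Their median was -0.64 in all libraries, with 28 below 0 (camera p = 1.31e-05, and 0.177 with an estimated correlation) and -0.23 without day 1 c, with 27 below 0 (p = 0.0257, and 0.119). Neither set decides: the whole list holds the genes that prompted it, and the 32 were left after the members with a call had been taken out, which lowers their fall. A shared fall of these genes may be present and stays open, and day 1 c carries much of its size.

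Of the 56 splits of the 8 libraries into 3 and 5, 2 gave at least the real 2 genes with the default filter, and the highest other split gave 15. With the stricter filter 1 of 56 gave as many as the real 146, and the highest other gave 23. Both shares lie under 0.05, the bound set beforehand, but this does not exclude chance or sample structure. With the default filter a split that mixes the days called more genes than the real one. The stricter count was given its place after the counts of all settings had been seen. Both of the highest other splits set day 1 b, day 1 c and day 3 b against the rest, the 3 libraries with the highest neutrophil sums. For the default filter that split calls several times the real count, which points to a structure of the samples. For lists called by camera, 4 of 56 splits gave at least the real 13, with 15 as the highest other, so chance cannot be excluded, and 53 of the other splits called at least 1 list, with a median of 7.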
